A study of Homo sapiens with 16 samples.

How the data were processed

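The samples were cultures of LX2, an established line of human hepatic stellate cells, the liver cells that turn into matrix-producing myofibroblasts when activated. Per the labels, cells were seeded, kept in serum for 24 h and starved of serum for 16 h. They were then left untreated, exposed to 50 mM ethanol for 24 h, given 10 µM of a small-molecule inhibitor of STING for 3 h before the same ethanol dose, or given the inhibitor without ethanol. STING is the adaptor protein that passes the signal of the DNA sensor cGAS on to the kinase TBK1 and the transcription factor IRF3. Each of the 4 groups held 4 libraries, 16 in all, and the group of every library was taken from its title and treatment label. The labels hold some conflicts: the series design text names TGFβ in place of ethanol, the titles of the control samples give 16 h where their time label gives 24 h, and the code of the inhibitor is spelled in more than one way. The short form STX in the titles was taken as the inhibitor named in the treatment protocol. The treatment label of the controls is untreated and names no vehicle, so effects of a solvent cannot be told apart from those of the inhibitor. Whether STING was blocked was not measured here. No label says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

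Per the labels' protocols, total RNA was extracted on columns, poly(A) RNA was selected with oligo(dT) beads, and stranded mRNA libraries were sequenced in paired-end mode on an Illumina NovaSeq instrument. The submitters' processing notes name cutadapt, HISAT2, StringTie, edgeR and the genome build GRCh38, without their roles or versions. The counting step, its strand setting and the annotation release are not given in the sources used here. The authors deposited a table of whole-number read counts for 63187 Ensembl gene IDs, which was the input of every main test, with 0 entries that named no gene. The authors deposited a further table of 25437 genes whose signal is each count divided by 1 factor per library. Within each library the ratio of signal to count was constant over genes, with a largest relative deviation of 5.8e-10. The factor matched the median-ratio size factor computed from the counts to the digits compared. The table listed genes with 10 or more counts over all libraries. It supplied gene symbols, biotypes and GRCh38 coordinates and served for 1 alternative test. Of the genes tested, 1404 had no symbol.

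Library totals lay between 15853432 and 24386437 counts. Levels are given in CPM, a gene's counts scaled to the library total multiplied by the library's TMM scaling factor. That factor lay between 0.8824 in ethanol plus inhibitor library 1 and 1.118 in inhibitor library 4. A group in which all libraries are at 0 was given a floor of 3 counts over the group, which covers counting error only. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group, which left 16082, libraries were scaled with TMM, and a single quasi-likelihood model with a mean per group was fitted to all 16 libraries (12 residual degrees of freedom, common biological coefficient of variation 15%). The 5 pairwise comparisons and the interaction of ethanol and inhibitor were contrasts of that model, tested with the two-sided quasi-likelihood F-test. P-values were adjusted with the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were taken as the fold change divided by the square root of F. CPM are given as mean ± SD over the 4 libraries of a group.

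A set of 30 gene lists with 719 genes on matrix, stellate cell state, interferon, inflammation, stress, metabolism, growth and other liver cell types was fixed together with the tests, the named-gene rule and most alternatives before the data were examined. The list of hepatocyte markers had 1 gene with enough counts and was not tested as a list. Each of the other 29 lists was tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01, again with the correlation estimated per list, and with fry, adjusted over the lists within a comparison. Unless said otherwise the list p-value printed is that of camera at the preset correlation. Of the 67 list calls made at the preset correlation over all contrasts, 32 held with an estimated correlation. Members were counted as past the threshold over all genes tested and adjusted over the list alone. Genes were named by rule: in each comparison the 10 higher and 10 lower genes with the largest change that were called, had a symbol, reached a mean of 5 CPM and had no overlap between the libraries of both groups (5 and 5 for the interaction, without the overlap condition), up to 4 members per described list by adjusted p, and a set of fixed genes of fibrosis, the STING pathway, interferon response and ethanol metabolism. Some genes that these rules name are not reported here. IFNB1 and CYP2E1 were among the fixed genes and were not tested because of low counts. The transcript XIST and genes of the Y chromosome were left out of all tables. RPLP0P2, named by the rule, is a pseudogene whose counts may be shared with its parent gene, so its values are uncertain.

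Expression relative to the mean of all libraries was related to GC content in a way that differed between libraries, which was found in the data. GC content and length were taken from the longest transcript of each gene, coding ones first, in GENCODE release 29, and 15557 of the genes tested (96.74%) had a value. A correction chosen after seeing the data fitted, per library, natural splines with 5 degrees of freedom on GC content and log2 length to genes above 1 on the log2 CPM scale and passed the trend to edgeR as offsets. It lowered the common coefficient of variation to 8.46%. Values called corrected come from this fit. A correction of this kind also removes any treatment effect that follows GC content or length. Within each group libraries 1 and 2, and libraries 3 and 4, resembled each other more than the other pair, so all tests were also run within libraries 1 and 2 and within libraries 3 and 4 of every group, also chosen after seeing the data. These fits hold 2 libraries per group, picked because they were alike. Their p-values leave out the spread between pairs, so they can call too many genes. Other alternatives were DESeq2 1.42.0 size factors in edgeR, the DESeq2 Wald test, limma on log2 of the deposited signal plus 1, no filter, a filter of 1 CPM in 4 libraries, the replicate number as a block, a fit to the compared groups only, and leaving out each library in turn.

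The tests were first run on simulated counts with known changes. For ethanol against control, edgeR called 78% of 50 genes changed 2-fold, 20% of 50 changed 1.5-fold and 0% of 50 changed 1.2-fold among 15671 simulated genes, with 3 false calls. In counts simulated with the observed GC and length trends and no change of any gene, the uncorrected test called 0 of 15694 genes for ethanol against control but 9183 for ethanol plus inhibitor against ethanol, 8544 for inhibitor against control, 11758 for ethanol plus inhibitor against inhibitor, 5822 for ethanol plus inhibitor against control and 10938 for the interaction, while the corrected test called 0 in each. The correction refits the form of trend that was simulated, so its 0 calls were fixed in advance. They do not show that corrected counts of real data are free of bias. The same uncorrected simulations called 0, 0, 0, 1, 2 and 0 lists in the order ethanol against control, ethanol plus inhibitor against ethanol, inhibitor against control, ethanol plus inhibitor against inhibitor, ethanol plus inhibitor against control, and interaction. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.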

Results

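Poly(A) RNA was sequenced from LX2 cells in a design of ethanol by STING inhibitor, with 4 libraries in each of the groups control, ethanol, ethanol plus inhibitor, and inhibitor. The control libraries held 16228982 to 23310416 counts and the ethanol libraries 15853432 to 20014747. The ethanol plus inhibitor libraries held 19763978 to 24386437 and the inhibitor libraries 17077872 to 23103266. STING1 itself (ENSG00000184584, GRCh38 chromosome 5, 139475533 to 139482936) was expressed at 54.9 ± 1.32 CPM in control, 53.4 ± 9.69 with ethanol, 75.7 ± 17.6 with ethanol plus inhibitor and 33.9 ± 2.3 with inhibitor (mean ± SD, n = 4).

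The libraries differed along an axis of GC content. Across genes, expression relative to the mean of all libraries correlated with GC content at Spearman's rho of 0.127 to 0.265 in the control libraries, -0.764 to -0.698 in the inhibitor libraries and 0.457 to 0.788 in the ethanol plus inhibitor libraries. The ethanol libraries were split, with -0.612 and -0.626 in libraries 1 and 2 against 0.348 and 0.0312 in libraries 3 and 4. Genes are not independent replicates in these correlations. The first principal component held 60.3% of the variance, and its loadings had a rho of -0.82 with GC content. Counts of library pairs differed by more than sampling noise in every group, with chi-square per degree of freedom of 2.12 to 5.8 within the pairs 1 and 2 or 3 and 4. Across these pairs it was 6.94 to 11.6 in control, 23.95 to 37.9 in ethanol, 45.9 to 79.3 in ethanol plus inhibitor and 3.5 to 5.09 in inhibitor, so for part of the results values within each pair or after correction for GC content and length are given too.

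**Figure D1:**
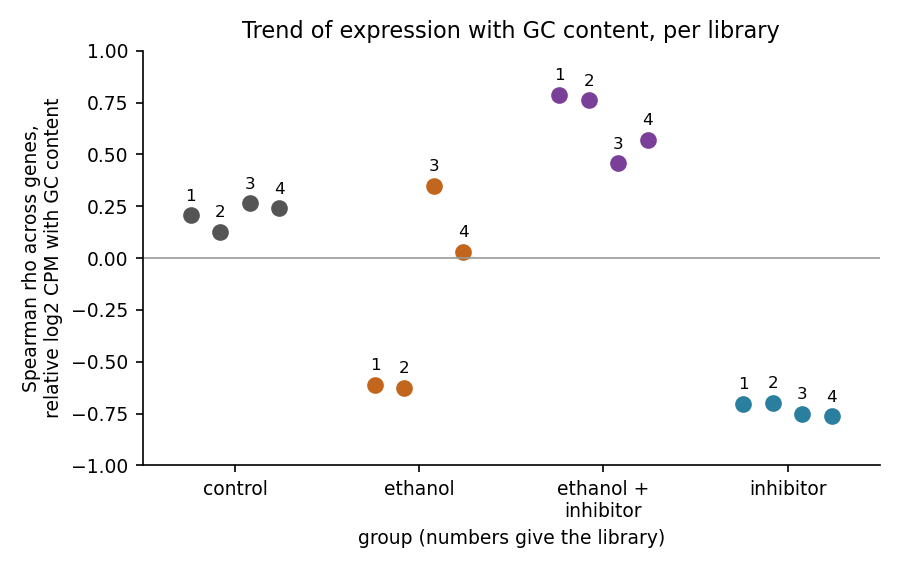
Spearman correlation across genes (y axis, from -1 to 1) between GC content and the log2 CPM of each library relative to the mean of all libraries, by group (x axis), with 1 point per library numbered by its replicate. The inhibitor libraries lie between -0.764 and -0.698, the ethanol plus inhibitor libraries between 0.457 and 0.788, and the ethanol libraries on both sides of 0.

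The comparison of ethanol with control addressed the response of stellate cells to ethanol. The collagenase gene MMP1 (ENSG00000196611, chromosome 11, 102789401 to 102798161) rose from 202 ± 12.4 to 587 ± 21.5 CPM (mean ± SD, n = 4), a log2 fold change of 1.54 ± 0.07 (SE, edgeR adjusted p = 1.69e-09). The stromelysin gene MMP3 rose with it, by 1.14 ± 0.16. Interferon-stimulated genes rose as well, among them IFI44L by 1.59 ± 0.15 and IFI44 (ENSG00000137965, chromosome 1, 78649796 to 78664079) by 1.04 ± 0.10, from 14.85 ± 0.731 to 30.58 ± 4.0 CPM (edgeR adjusted p = 1.05e-05). Glycolytic genes fell: PGK1, phosphoglycerate kinase (ENSG00000102144, chromosome X, 77910739 to 78129296), went from 1708 ± 22.4 to 842 ± 163 CPM, a change of -1.02 ± 0.11 (edgeR adjusted p = 2.68e-05). ACTA2, the smooth muscle actin that marks activated stellate cells (ENSG00000107796, chromosome 10, 88935074 to 88991340), fell from 26.93 ± 1.76 to 15.11 ± 2.31 CPM, a change of -0.83 ± 0.14 (edgeR adjusted p = 0.00215). The fibrillar collagen genes did not pass the test, with COL1A1 at -0.13 ± 0.12, COL1A2 at 0.01 ± 0.12 and COL3A1 at 0.15 ± 0.11 (edgeR adjusted p = 0.52, 0.975 and 0.442). The library pairs disagreed on them: within libraries 1 and 2 COL1A1 was lower (-0.439, adjusted p = 1.17e-09) and COL3A1 at -0.0527 (0.278), while within libraries 3 and 4 both were higher (0.150 and 0.338, adjusted p = 0.0249 and 7.6e-06). COL1A2 was at -0.126 and 0.123 in the pairs (0.103 and 0.268). Adjusted p-values within a pair leave out the larger spread between the pairs. After correction the 3 genes were at 0.04, 0.10 and 0.19 over all libraries (adjusted p = 0.687, 0.309 and 0.131). Both pairs agreed on MMP1 (1.59 and 1.48), IFI44 (1.12 and 0.944), PGK1 (-1.28 and -0.813) and ACTA2 (-1.02 and -0.675).

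Among the genes with the largest rise with ethanol were also SERPINB2, an inhibitor of plasminogen activation, at 1.22 ± 0.09, the collagen-binding integrin gene ITGA2 at 1.14 ± 0.14, the tight junction gene CLDN1 at 1.02 ± 0.11 and the prolactin receptor gene PRLR at 1.02 ± 0.20. The cystine transporter gene SLC7A11 rose by 1.01 ± 0.16 and ANKRD36B by 0.98 ± 0.20. The largest falls were those of PPFIA4 (-2.33 ± 0.32), the mitochondrial adenylate kinase gene AK4 (-1.41 ± 0.28), VSIR (-1.33 ± 0.19), the mitophagy receptor gene BNIP3 (-1.30 ± 0.20) and the secretory kinase gene FAM20C (-1.30 ± 0.13). They were followed by SPAG4 (-1.25 ± 0.13), the aldolase gene ALDOC (-1.21 ± 0.12), the lactate exporter gene SLC16A3 (-1.18 ± 0.12), RRAD (-1.08 ± 0.17) and TMEM45A (-1.06 ± 0.20). Sizes depended on the library pair for SLC7A11 (1.30 in libraries 1 and 2, 0.61 in libraries 3 and 4), PRLR (1.21 and 0.785), PPFIA4 (-2.92 and -1.87), FAM20C (-1.63 and -1.03), SPAG4 (-1.49 and -1.0), ALDOC (-1.51 and -0.964), SLC16A3 (-1.54 and -0.847) and RRAD (-1.40 and -0.811). After correction over all libraries these were 0.66, 0.71, -2.19, -1.07, -0.99, -1.04, -0.97 and -0.82 in this order. CXCL10, an interferon-induced chemokine gene near the detection limit, was at 0.511 ± 0.142 CPM in control and 1.51 ± 0.069 with ethanol. Its adjusted p in edgeR was 0.0258, but 0.0512 to 0.0882 on leaving out any control library or ethanol library 1, 2 or 4, when the call was lost. IFIT1 (0.35 ± 0.15), ISG15 (0.26 ± 0.27), IL6 (0.66 ± 0.23), CXCL8 (0.10 ± 0.14), CCL2 (-0.11 ± 0.17) and the aldehyde dehydrogenase gene ALDH2 (0.04 ± 0.10) did not pass, although ISG15 did after correction (0.54, adjusted p = 0.00706 in edgeR). Within both library pairs IL6 (0.354 and 0.900, adjusted p = 4.65e-06 and 1.83e-10) and IFIT1 (0.398 and 0.310, adjusted p = 0.00111 and 0.0343) were called higher. These p-values leave out the spread between the pairs.

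By list, 16 of 49 interferon-stimulated genes rose with ethanol (26 adjusted over the list alone), with a median of 0.40. Its camera adjusted p was 8.61e-19, and 9.82e-04 with an estimated correlation. TRIM22 (0.74 ± 0.09) and IFIT3 (0.63 ± 0.09) were among them. The list median was 0.40 in libraries 1 and 2 (25 higher, 11 lower) and 0.48 in libraries 3 and 4 (34 and 0), where the correction left 19 higher and 5 lower, and 40 and 0. Over all libraries it was 0.34 after correction, with 22 genes risen (adjusted p = 0.0214 with an estimated correlation). Of 30 genes of hypoxia and glycolysis, 17 fell (20 adjusted over the list alone), with a median of -0.62. Camera gave an adjusted p of 1.5e-36 for this list, and of 0.00575 with an estimated correlation. ENO2 (-0.88 ± 0.09), ALDOC, SLC16A3 and PGK1 led this list, whose median was -0.86 and -0.45 in the library pairs and -0.52 after correction. Of 11 aryl hydrocarbon receptor and xenobiotic genes 4 rose (5 adjusted over the list alone), led by the cytochrome gene CYP1B1 at 1.40 ± 0.27. These genes include the receptor gene AHR itself, so their list is wider than targets of the receptor. Their median was 0.42 and their camera adjusted p 7.87e-05, or 0.00575 with an estimated correlation. Their median was 0.514 and 0.317 in the library pairs and 0.41 after correction (adjusted p = 0.0374 with an estimated correlation). Those are the 3 lists whose call in this comparison held with an estimated correlation as counted, and each held after correction too.

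Matrix proteases and their inhibitors rose in 5 of 21 cases and fell in 2 (7 and 2 adjusted over the list alone), with MMP1, MMP3 and SERPINE2 (0.39 ± 0.06) higher and TIMP3 (-0.43 ± 0.09) lower. The list had a camera adjusted p of 1.84e-05, and of 0.136 with an estimated correlation. Its median was 0.0218 in libraries 1 and 2 (7 higher, 8 lower) and 0.345 in libraries 3 and 4 (12 and 2). After correction 10 rose and 1 fell, with an adjusted p of 0.0374 with an estimated correlation. Of 37 NF-kB and inflammatory genes 6 rose and 1 fell (15 and 3 adjusted over the list alone), including the prostaglandin synthase gene PTGS2 (1.03 ± 0.14), the chemokine genes CXCL2 (0.53 ± 0.08) and CXCL3 (0.67 ± 0.12) and the caspase gene CASP1 (0.67 ± 0.13). Their camera adjusted p was 1.2e-04, and 0.182 with an estimated correlation, or 0.282 after correction. Here too the pairs differed, with medians of 0.0614 (13 higher, 11 lower) and 0.355 (21 and 1). Immediate early genes rose in 7 of 29 cases (8 higher and 3 lower adjusted over the list alone), with the feedback inhibitors SPRY2 (0.79 ± 0.09), SPRY4 (0.49 ± 0.07) and DUSP6 (0.72 ± 0.10) and the transcription factor KLF4 (0.70 ± 0.09). By camera, the list's adjusted p was 1.69e-04, and 0.245 with an estimated correlation. The median was -0.00533 in libraries 1 and 2 (8 higher, 10 lower) and 0.275 in libraries 3 and 4 (13 and 2), and with the correction 0.212 and 0.309. Over all libraries 13 rose and 0 fell after correction, with an adjusted p of 0.00169 with an estimated correlation. NRF2 targets rose in 6 of 27 cases and fell in 1 (7 and 1 adjusted over the list alone), among them the thioredoxin reductase gene TXNRD1 (0.52 ± 0.10). For the list, camera's adjusted p was 0.00974, and 0.269 with an estimated correlation, or 0.208 after correction, with medians of 0.0769 and 0.147 in the pairs. Stellate activation and contractile genes fell in 6 of 23 cases and rose in 1 (7 and 2 adjusted over the list alone), with MYL9 at -0.67 ± 0.13 and ACTN1 at -0.37 ± 0.08 beside ACTA2, and GREM1, a BMP antagonist, higher at 0.72 ± 0.07. Its camera adjusted p was 0.0402, and 0.157 with an estimated correlation, or 0.0402 after correction, with medians of -0.304 and -0.0554 in the pairs. Genes of fatty acid synthesis and lipid droplets fell in 4 of 23 cases (4 adjusted over the list alone), including the lipid droplet genes PLIN2 (-0.55 ± 0.08) and HILPDA (-0.57 ± 0.11). Camera gave an adjusted p of 0.00631 for this list, and of 0.157 with an estimated correlation, or 0.282 after correction, with medians of -0.311 and -0.078 in the pairs.

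Collagens and matrix were not past the threshold as a list (median -0.08, camera adjusted p = 0.246), with TNC higher (0.35 ± 0.07) and P4HA2 (-0.64 ± 0.10), LOXL2 (-0.56 ± 0.11) and 1 more of 32 lower (3 higher and 3 lower adjusted over the list alone). Nor were TGF-beta targets (3 higher and 2 lower of 29, 6 and 3 adjusted over the list alone, camera adjusted p = 0.31), with TGFBI lower at -0.58 ± 0.10. For the 23 members of the cGAS-STING pathway, edgeR called 0 genes, also when adjusted over the list alone, where 9 had an unadjusted p under 0.05 and DESeq2 called 2. STING1 stood at -0.04 ± 0.15, CGAS at -0.14 ± 0.11, TBK1 at 0.62 ± 0.24 and IRF3 at -0.22 ± 0.14 (edgeR adjusted p = 0.892, 0.466, 0.181 and 0.373). After correction CGAS was lower (-0.27, adjusted p = 0.0394) and 1 other member higher, with STING1 at 0.14, TBK1 at 0.38 and IRF3 at 0.02 (0.123, 0.052 and 0.887). Within libraries 1 and 2 as counted STING1 (-0.292) and IRF3 (-0.457) were lower (adjusted p = 4.65e-04 and 1.82e-06), and within libraries 3 and 4 they were at 0.175 and -0.0215 (0.0916 and 0.892). TBK1 was higher in both pairs (0.807 and 0.338, adjusted p = 2.08e-08 and 0.0214). These p-values within pairs leave out the spread between the pairs.

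With ethanol, edgeR called 479 of 16082 genes, 272 higher (56.78%) and 207 lower, 83 of them at least 2-fold. After correction it called 1461 genes, of which 43.94% were higher, and 408 were called the same way in both. The count was 287, 293, 247 and 258 without control 1 to 4, 236 and 233 without ethanol 1 and 2, and 812 (49.51% higher) without ethanol 3. It was 8039 within libraries 1 and 2 and 1975 within libraries 3 and 4, and 3747 and 2700 after correction. Both pairs called 704 genes higher and 541 lower, and called 239 in opposite directions. After correction these numbers were 583, 855 and 98.

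**Figure D2:**
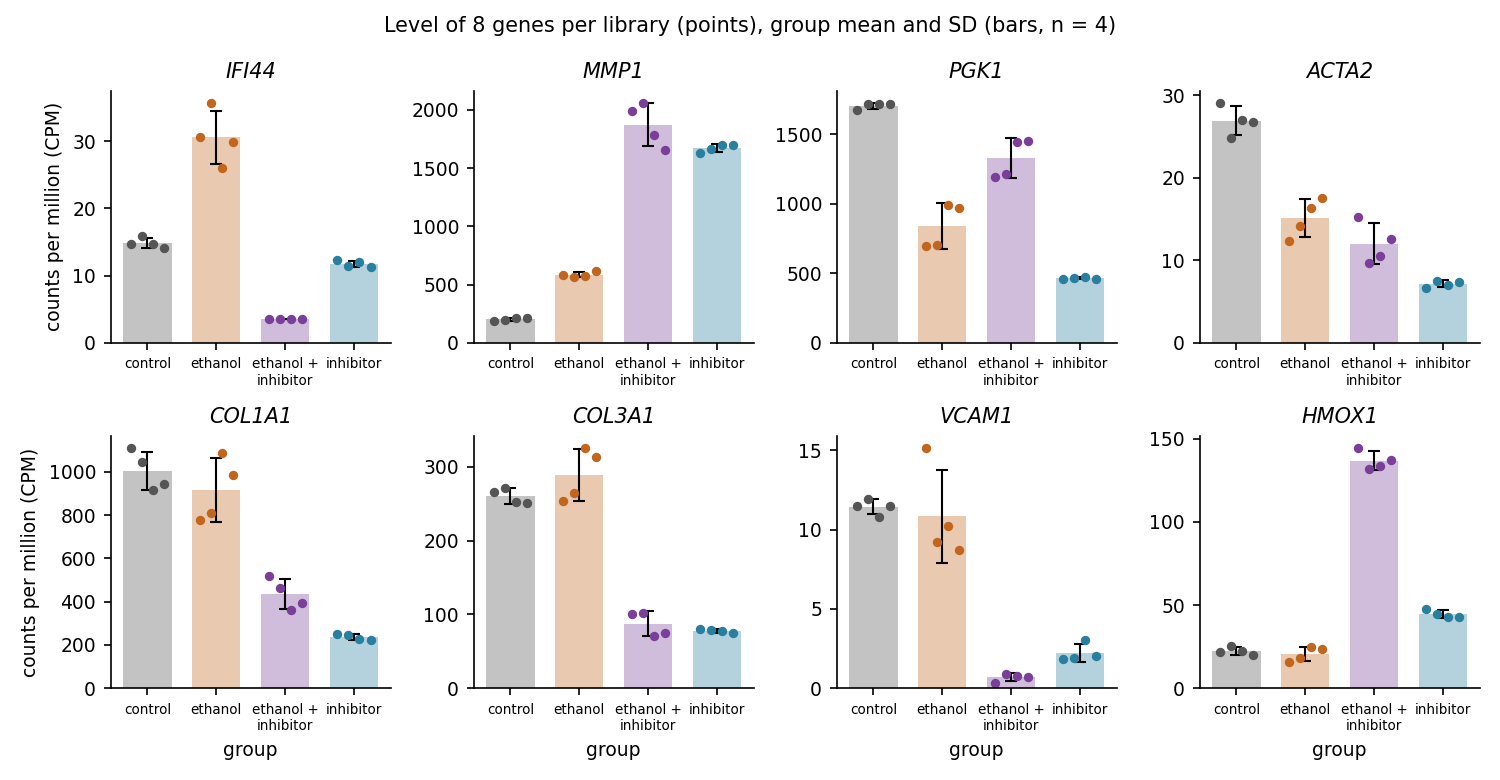
Expression in CPM (y axis, from 0) of IFI44, MMP1, PGK1, ACTA2, COL1A1, COL3A1, VCAM1 and HMOX1 in the 4 groups (x axis), with points for libraries and bars for mean ± SD (n = 4). MMP1 rises from a mean of 202 in control to 587 with ethanol and 1872 with ethanol plus inhibitor, while COL3A1 goes from 260 in control to 87.5 with ethanol plus inhibitor.

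The inhibitor without ethanol gave the background for its action on ethanol-treated cells. The fibrillar collagen genes fell: COL1A1 (ENSG00000108821, chromosome 17, 50184101 to 50201633) went from 1004 ± 89.8 to 236 ± 14.7 CPM, a change of -2.09 ± 0.12. COL3A1 (ENSG00000168542, chromosome 2, 188974373 to 189012747) went from 260 ± 10.4 to 77.6 ± 2.32 CPM, a change of -1.75 ± 0.12, with edgeR adjusted p of 1.62e-09 and 5.05e-09 for both genes in this order. ACTA2 (-1.92 ± 0.14) and COL1A2 (-1.69 ± 0.12) fell with them. After correction these 4 genes were at -1.57, -1.60, -1.59 and -1.38. MMP1 rose to 1671 ± 30.8 CPM (3.05 ± 0.08, edgeR adjusted p = 3.73e-14) and MMP3 by 2.51 ± 0.16.

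Other large rises with the inhibitor were those of the pappalysin gene PAPPA2 (3.32 ± 0.16), SLC7A11 (2.99 ± 0.17), the pseudogene RPLP0P2 (2.99 ± 0.14), osteopontin SPP1 (2.83 ± 0.13), RND3 (2.54 ± 0.23), PCDH9 (2.49 ± 0.18), MCTP1 (2.43 ± 0.19) and the cytokine gene IL24 (2.31 ± 0.36). Large falls also took in the interferon-induced genes MX2 (-2.70 ± 0.17) and OASL (-2.37 ± 0.29) and the sterol synthesis genes MVD (-2.69 ± 0.14) and DHCR7 (-2.45 ± 0.12). Further falls were those of ALDOC (-2.65 ± 0.13), TINAGL1 (-2.64 ± 0.21), PPFIA4 (-2.51 ± 0.32), the keratin gene KRT80 (-2.37 ± 0.17) and the adhesion molecule VCAM1 (-2.37 ± 0.21). After correction SLC7A11 was at 2.10, RND3 at 1.87, PCDH9 at 1.52, MVD at -2.0, TINAGL1 at -1.99 and VCAM1 at -2.90.

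Of 32 collagen and matrix genes, 25 fell (26 adjusted over the list alone), with THBS2 (-1.44 ± 0.10) and COL4A1 (-1.01 ± 0.07) among them. Their median was -1.0, or -0.70 after correction, and their camera adjusted p 3.87e-15, or 0.00318 with an estimated correlation. Stellate activation and contractile genes fell in 14 of 23 cases and rose in 2, also when adjusted over the list alone, with a median of -0.98, or -0.55 after correction. The list had a camera adjusted p of 1.5e-05, and of 0.00536 with an estimated correlation. Cholesterol synthesis fell furthest, in 23 of 26 genes with 1 higher, including ACAT2 (-2.11 ± 0.10) and FDFT1 (-1.97 ± 0.10). Its median was -1.53, or -1.43 after correction and -1.41 and -1.54 in the library pairs. Camera gave it an adjusted p of 3.2e-29, and of 6.36e-05 with an estimated correlation. The fatty acid synthesis genes FASN (-1.99 ± 0.12), FADS2 (-2.23 ± 0.14) and SCD (-1.65 ± 0.08) were among 14 of 23 genes of their list that fell, with 3 higher. By camera, the list's adjusted p was 1.37e-06, and 0.0118 with an estimated correlation.

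Interferon-stimulated genes fell in 33 of 49 cases and rose in 5 (34 and 5 adjusted over the list alone), with a median of -0.89 and OAS3 (-1.72 ± 0.11), OAS2 (-2.04 ± 0.15) and IFIT1 (-2.02 ± 0.16) among them. For the list, camera's adjusted p was 2.38e-07, and 0.0115 with an estimated correlation. After correction the median was -0.68 and the adjusted p 0.0558 with an estimated correlation. Hypoxia and glycolysis genes fell in 21 of 30 cases and rose in 2, with a median of -1.13, PGK1 at -1.87 ± 0.11 and PFKFB4 at -1.75 ± 0.11. Its camera adjusted p was 2.83e-15, and 0.0303 with an estimated correlation. The corrected median was -0.70, with an adjusted p of 0.0983 with an estimated correlation. Cell cycle genes fell in 23 of 36 cases and rose in 2, with the mitotic genes KIF20A (-1.89 ± 0.09), PLK1 (-2.12 ± 0.13) and CCNB1 (-1.32 ± 0.07). Their median was -0.58, or -0.74 after correction, and their camera adjusted p 3.87e-11, or 0.00595 with an estimated correlation. Replication-dependent histone genes fell in 10 of 10 cases, by a median of -1.33, with H2BC21 at -2.02 ± 0.13 and H1-2 at -1.99 ± 0.15. Camera gave an adjusted p of 2.01e-07 for this list, and of 0.00318 with an estimated correlation. After correction 9 of 10 fell, by a median of -0.72 (camera adjusted p = 0.0013 with an estimated correlation).

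Targets of ATF4, the transcription factor of the integrated stress response, rose in 16 of 31 cases and fell in 3, with a median of 0.44. The list had a camera adjusted p of 4.66e-05, and of 0.0641 with an estimated correlation. After correction 22 rose and 1 fell, with a median of 0.62 (adjusted p = 1.11e-04 with an estimated correlation). SLC3A2, the heavy chain of the cystine and leucine transporters, rose by 2.21 ± 0.12 and ALDH1L2 by 1.84 ± 0.17. Aryl hydrocarbon receptor and xenobiotic genes rose in 9 of 11 cases, with CYP1B1 at 1.64 ± 0.26 and a median of 0.83. Their camera adjusted p was 0.00161, or 0.0133 with an estimated correlation, and after correction the latter was 0.0783. NRF2 targets rose in 14 of 27 cases and fell in 6, with TXNRD1 at 1.48 ± 0.10 and AKR1C1 at 1.87 ± 0.14. By camera, the list's adjusted p was 0.00302, and 0.214 with an estimated correlation. YAP and SRF targets fell in 14 of 22 cases and rose in 4, with ACTG2 at -1.79 ± 0.11. For the list, camera's adjusted p was 4.99e-04, and 0.023 with an estimated correlation. After correction the latter was 0.0802. The 37 NF-kB and inflammatory genes went both ways, 15 higher and 15 lower (camera adjusted p = 0.777), with PTGS2 (1.68 ± 0.14), CXCL2 (0.97 ± 0.08) and IL1B (0.85 ± 0.07) higher and CCL2 (-2.13 ± 0.17) lower. STING1 was at -0.70 ± 0.15 as counted and -0.15 after correction, while IRF3 was at -0.72 ± 0.14 and -0.03 and TIMP1 at -0.48 ± 0.19 and 0.20.

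The test of inhibitor against control called 9783 genes, 4708 higher and 5075 lower, 2291 of them at least 2-fold. The log2 fold changes had a Spearman's rho of -0.67 with GC content across genes, and 8154 genes were called after correction, 5410 of them the same way and 451 the opposite way.

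Ethanol plus inhibitor against ethanol asked what the inhibitor changed in the presence of ethanol. Interferon-stimulated genes fell the furthest: IFI44L went from 9.87 ± 0.962 to 0.384 ± 0.0899 CPM (-4.67 ± 0.19) and IFI44 from 30.58 ± 4.0 to 3.53 ± 0.0425 CPM (-3.11 ± 0.11), with edgeR adjusted p of 4.44e-11 and 8.35e-12. CXCL10 had 0 counts in each ethanol plus inhibitor library, at least 42.1-fold lower than with ethanol, taking 3 counts over the group as the floor. COL1A1 fell from 916 ± 147 to 435 ± 69.9 CPM (-1.07 ± 0.12) and COL3A1 from 289 ± 35.2 to 87.5 ± 16.7 CPM (-1.73 ± 0.12), with edgeR adjusted p of 2.02e-06 and 7.78e-09. Within libraries 1 and 2 these falls were -0.694 and -1.35, within libraries 3 and 4 -1.45 and -2.12, and after correction -1.44 and -1.83. The amino acid transporter gene SLC3A2 (ENSG00000168003, chromosome 11, 62856004 to 62888881) rose from 251 ± 41.3 to 3005 ± 554 CPM (3.58 ± 0.13, edgeR adjusted p = 9.19e-12). The heme oxygenase gene HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35394215) rose from 20.5 ± 4.25 to 137 ± 5.61 CPM (2.74 ± 0.13, edgeR adjusted p = 1.03e-10).

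Further genes with large rises were CRYM (3.26 ± 0.19), the PPAR target ANGPTL4 (3.03 ± 0.29), PAPPA2 (2.86 ± 0.16), RPLP0P2 (2.80 ± 0.14), the stress-induced pseudokinase gene TRIB3 (2.50 ± 0.15), MC5R (2.50 ± 0.21), the NRF2 target AKR1C1 (2.48 ± 0.14) and PCDH1 (2.23 ± 0.17). Large falls were those of VCAM1 (-3.94 ± 0.25), the interferon-induced genes DDX60 (-3.93 ± 0.24), OAS2 (-3.31 ± 0.16), MX2 (-3.17 ± 0.17), SAMD9L (-2.98 ± 0.21) and IFIT2 (-2.90 ± 0.14), and the spindle gene ASPM (-3.01 ± 0.29). After correction these falls were -3.37, -2.93, -3.14, -3.34, -1.89, -2.40 and -1.75 in this order. The library pairs gave -4.07 and -2.07 for ASPM, -3.61 and -2.35 for SAMD9L and -4.68 and -3.23 for DDX60. Corrected values were also smaller for IFI44L (-3.64), IFI44 (-2.45), SLC3A2 (2.97), HMOX1 (2.13), ANGPTL4 (2.22) and TRIB3 (1.81), and larger for AKR1C1 (3.25).

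Of 49 interferon-stimulated genes, 37 fell and 2 rose, also when adjusted over the list alone, with a median of -1.58. Its camera adjusted p was 2.05e-28, and 1.13e-04 with an estimated correlation. The median was -1.40 and -1.68 in the library pairs and -1.50 after correction, when 47 fell. Collagen and matrix genes fell in 22 of 32 cases and rose in 4 (23 and 4 adjusted over the list alone), with a median of -0.60, or -0.64 after correction, and COL4A1 (-1.01 ± 0.07), LAMB1 (-1.11 ± 0.07) and THBS1 (-1.18 ± 0.07) among them. Camera gave an adjusted p of 7.97e-09 for this list, and of 0.0196 with an estimated correlation. ATF4 targets rose in 28 of 31 cases, also when adjusted over the list alone, with a median of 1.19, DDIT3 at 1.75 ± 0.14 and the alanyl-tRNA synthetase gene AARS1 at 1.23 ± 0.10. The list had a camera adjusted p of 1.78e-15, and of 0.00415 with an estimated correlation. Their median was 1.55 in libraries 1 and 2, 0.77 in libraries 3 and 4 and 0.83 after correction. Cholesterol synthesis fell in 21 of 26 genes and rose in 1 (22 and 1 adjusted over the list alone), by a median of -0.72, or -0.90 after correction, with HMGCS1 (-2.43 ± 0.22), INSIG1 (-1.28 ± 0.09) and SQLE (-1.09 ± 0.09) lower. By camera, the list's adjusted p was 3.22e-08, and 0.00625 with an estimated correlation. NRF2 targets rose in 19 of 27 cases and fell in 1, also when adjusted over the list alone, by a median of 0.68, or 0.48 after correction, with the ferritin gene FTL (1.78 ± 0.16) and the autophagy receptor gene SQSTM1 (1.62 ± 0.15) higher. For the list, camera's adjusted p was 6.2e-08, and 0.0267 with an estimated correlation.

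Cell cycle genes fell in 21 of 36 cases and rose in 10, with the proliferation marker MKI67 (-2.29 ± 0.14), TOP2A (-2.71 ± 0.21) and KIF20A (-1.53 ± 0.09) lower. Its camera adjusted p was 7.94e-06, and 0.0247 with an estimated correlation. After correction 27 fell and 4 rose. Replication-dependent histone genes fell in 8 of 10 cases and rose in 1, with H2BC21 at -1.58 ± 0.13. Camera gave an adjusted p of 8.95e-04 for this list, and of 0.0267 with an estimated correlation. Genes of the unfolded protein response rose in 16 of 27 cases and fell in 5, with the chaperone gene HSPA5 at 1.46 ± 0.09 and HERPUD1 at 1.46 ± 0.08. The list had a camera adjusted p of 6.06e-06, and of 0.158 with an estimated correlation. Hypoxia and glycolysis genes rose in 20 of 30 cases and fell in 2, with VEGFA at 1.10 ± 0.11. Here the median was 0.52 and the camera adjusted p 5.9e-04, or 0.321 with an estimated correlation. Their median was 0.18 after correction (camera adjusted p = 0.06), and 0.02 in libraries 1 and 2 against 0.40 in libraries 3 and 4. Stellate activation genes went both ways, 6 higher and 10 lower of 23 (camera adjusted p = 0.0962), with the kinase gene MYLK at -1.39 ± 0.08, and after correction 2 rose and 12 fell (adjusted p = 0.0308 with an estimated correlation). Matrix proteases and inhibitors rose in 11 of 21 cases and fell in 5, with MMP1 at 1.67 ± 0.07 and MMP3 at 1.83 ± 0.15. By camera, the list's adjusted p was 0.0225, and 0.321 with an estimated correlation. After correction 11 rose and 7 fell, and camera did not call the list (adjusted p = 0.428). Of 37 NF-kB and inflammatory genes 14 rose and 16 fell (camera adjusted p = 0.152), with CXCL6 (-2.16 ± 0.13), TNFAIP6 (-2.63 ± 0.18) and CCL2 (-2.53 ± 0.18) lower and CXCL8 (0.93 ± 0.14) higher. In the cGAS-STING pathway 13 of 23 genes rose and 6 fell (camera adjusted p = 0.561), with SAMHD1 (-1.10 ± 0.07), IFI16 (-1.39 ± 0.18) and TBK1 (-1.81 ± 0.25, or -1.03 after correction) lower. After correction 10 of these genes rose and 9 fell (camera adjusted p = 0.858), and the median went from 0.32 to 0.02. STING1 was at 0.50 ± 0.14 as counted and -0.12 after correction, and IRF3 at 0.85 ± 0.14 and 0.10. CGAS was higher, at 0.254 as counted and 0.608 after correction (edgeR adjusted p = 0.0464 and 2.46e-06).

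The comparison called 10417 genes, 5240 higher and 5177 lower, 3263 of them at least 2-fold, and after correction 8848, of which 5885 were called the same way and 842 the opposite way as before it. Log2 fold changes had a rho of 0.69 with GC content across genes.

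**Figure D3:**
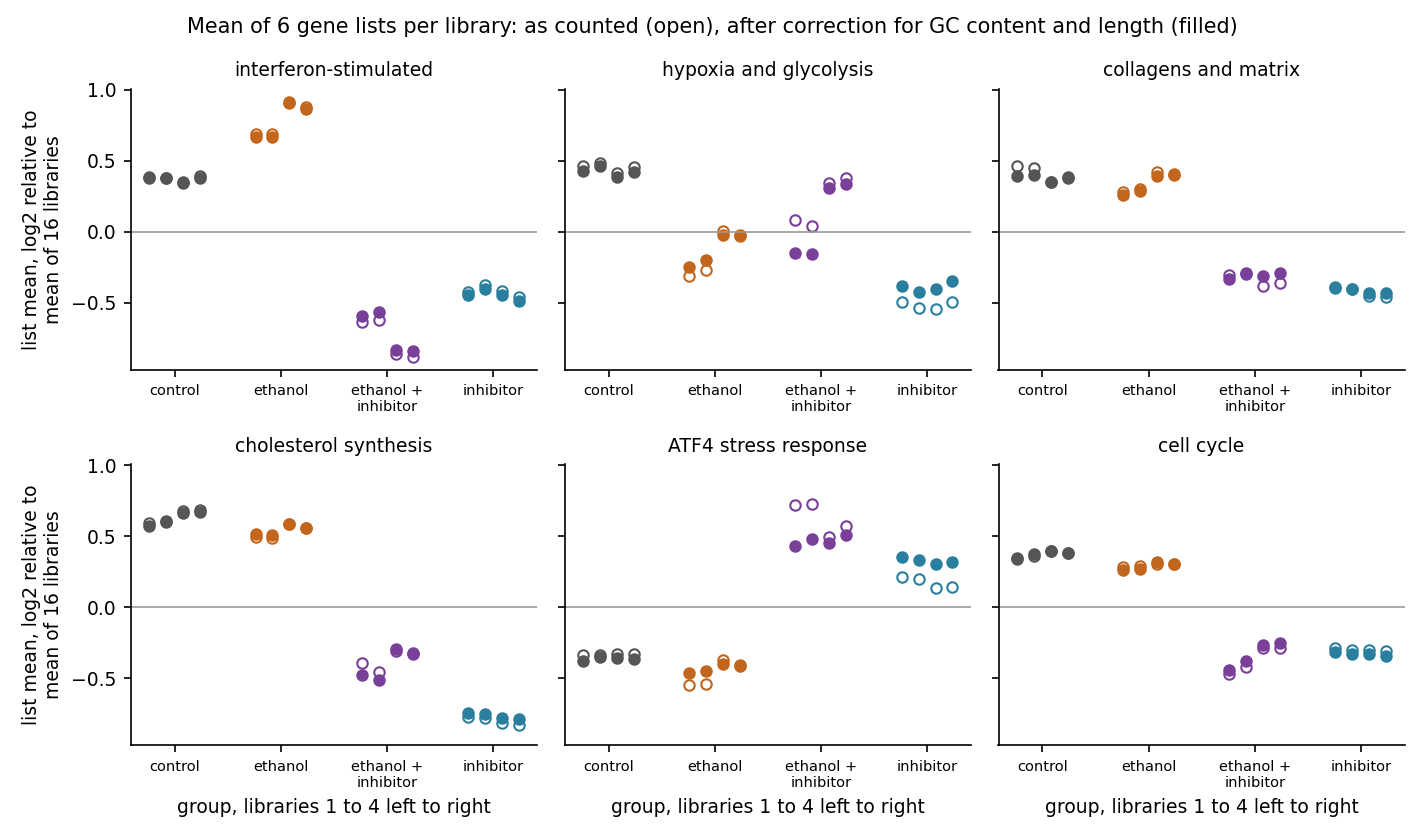
Mean over the genes of 6 lists of log2 expression relative to the mean of all 16 libraries (y axis), for each library of the 4 groups (x axis, libraries 1 to 4 from left to right), as counted (open symbols) and corrected for GC content and length (filled symbols). As counted, interferon-stimulated genes lie at 0.69 to 0.91 in the ethanol libraries, 0.35 to 0.39 in control and -0.88 to -0.62 with ethanol plus inhibitor.

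Of the 479 genes called with ethanol, 325 (67.8%) were called in the opposite direction between ethanol plus inhibitor and ethanol, 178 of the 272 higher and 147 of the 207 lower genes. Both comparisons use the same ethanol libraries. Independent lists of these sizes would share 155 genes, and 10 simulations of unchanged groups gave 0. With no effects edgeR calls next to no gene, so that 0 says nothing about the shared libraries. As counted, log2 fold changes followed GC content with opposite signs in these comparisons (rho -0.56 and 0.69). Independent lists leave out the opposite calls that such a trend would give. Fold changes correlated across genes at -0.54, against -0.51 in the simulations. Their covariance was -0.158, against -0.0273 simulated, a difference of -0.131. After correction the correlation was -0.36, against -0.52 in 10 simulations of the corrected fit, and the covariance -0.0686, against -0.0208 simulated, a difference of -0.0478. With 2 of the ethanol libraries in each comparison, the number of genes called with ethanol varied widely. Of these, 72 of 104, 73 of 111, 87 of 138, 94 of 147, 98 of 162 and 2635 of 4082 reversed. Independent lists would share 29.5, 31.32, 37.23, 39.42, 53.63 and 962.1 genes in this order. The correlation lay between -0.51 and -0.05. It was -0.51 with ethanol libraries 1 and 2 set against control, the split with 2635 of 4082. It was -0.05 with ethanol libraries 3 and 4 set against control, the split with 98 of 162. After correction 814 of 1461 genes (55.7%) reversed, where independent lists would share 404. With the split ethanol libraries, 258 of 519, 263 of 531, 272 of 531, 278 of 574, 292 of 654 and 1415 of 2664 reversed after correction. Independent lists would share 118.1 to 569.3 genes there. Of the 325 genes, 181 did not differ from control with ethanol plus inhibitor, 125 had passed to the other side of control and 19 were still off control on the first side. The 16 interferon-stimulated genes that rose with ethanol were all among the reversed genes (22 of 22 after correction), and 15 of the 17 fallen hypoxia and glycolysis genes were (8 of 21 after correction). Of all 49 interferon-stimulated genes, 37 fell between ethanol plus inhibitor and ethanol (47 after correction). Of all 30 hypoxia and glycolysis genes, 20 rose (9 after correction). Reversal of the interferon-stimulated genes was therefore likely whether or not ethanol had raised them. The number of reversed genes was 197, 205, 169 and 174 without control 1 to 4, 148 and 150 without ethanol 1 and 2, and 643 without ethanol 3.

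Ethanol plus inhibitor against control gave the joint effect of both treatments. SLC3A2 rose by 3.69 ± 0.13, MMP1 by 3.21 ± 0.08 to 1872 ± 187 CPM, AKR1C1 by 3.18 ± 0.15, MMP3 by 2.97 ± 0.16 and HMOX1 by 2.60 ± 0.13 (edgeR adjusted p = 6.11e-12, 1.72e-14, 1.38e-10, 7.91e-10 and 2.14e-10). RPLP0P2 (3.57 ± 0.14), PAPPA2 (3.39 ± 0.16), CRYM (3.35 ± 0.19), SYT7 (2.74 ± 0.25), MC5R (2.63 ± 0.21) and ANGPTL4 (2.61 ± 0.28) completed the largest rises. Among the largest falls were VCAM1 (-4.01 ± 0.24), DDX60 (-2.96 ± 0.24), ASPM (-2.66 ± 0.29), CCL2 (-2.63 ± 0.18), the guanylate-binding protein gene GBP4 (-2.45 ± 0.11), MX2 (-2.42 ± 0.17) and the mitotic genes DEPDC1 (-2.48 ± 0.21), HMMR (-2.39 ± 0.28) and CENPE (-2.38 ± 0.27). The correction reduced DDX60 to -2.23, ASPM to -1.74, GBP4 to -1.865, DEPDC1 to -1.59, HMMR to -1.76 and CENPE to -1.42, and left VCAM1 at -3.625, CCL2 at -2.28 and MX2 at -2.59. The library pairs gave -3.64 and -1.87 for ASPM, -3.03 and -2.05 for DEPDC1, -3.25 and -1.88 for HMMR and -3.36 and -1.59 for CENPE. COL1A1 (-1.21 ± 0.12), COL3A1 (-1.57 ± 0.12) and ACTA2 (-1.17 ± 0.14) fell as well.

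Interferon-stimulated genes were lower than control in 37 of 49 cases and higher in 2, with a median of -1.21, or -1.17 after correction (camera adjusted p = 6.98e-21). Collagens and matrix fell in 24 of 32 cases and rose in 1, with a median of -0.67 (camera adjusted p = 1.85e-14). Cholesterol synthesis fell in 24 of 26 genes with 1 higher, by a median of -0.92 (camera adjusted p = 5.16e-15), and the cell cycle in 24 of 36 with 4 higher, by a median of -0.54 (camera adjusted p = 1.24e-10). Targets of ATF4 rose in 28 of 31 cases, with a median of 0.91 (camera adjusted p = 1.85e-17), and NRF2 targets in 21 of 27 with 1 lower, with a median of 0.70 (camera adjusted p = 5.16e-15). With an estimated correlation the adjusted p was 4.96e-04 for interferon-stimulated genes, 9.86e-04 for cholesterol synthesis, 0.00195 for ATF4 targets, and 0.00341 for collagens and matrix, the cell cycle and NRF2 targets. The unfolded protein response rose in 20 of 27 genes with 2 lower, by a median of 0.48 (camera adjusted p = 3.33e-10). With an estimated correlation its adjusted p was 0.0461, and 0.0728 after correction. Hypoxia and glycolysis genes were not past the threshold, with 3 higher and 10 lower of 30 and a median of -0.09 (camera adjusted p = 0.265). After correction 3 were higher and 19 lower, with a median of -0.34 (camera adjusted p = 0.00215, or 0.562 with an estimated correlation). This comparison called 8637 genes, 4279 higher and 4358 lower, 2000 of them at least 2-fold, and 8136 after correction, with a rho of 0.59 between log2 fold change and GC content.

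Ethanol plus inhibitor against inhibitor gave the effect of ethanol in inhibitor-treated cells, where genes of hypoxia and glycolysis were higher. PGK1 rose from 466 ± 6.14 to 1330 ± 142 CPM (1.51 ± 0.11), or by 2.33 after correction, and SLC16A3 by 1.76 ± 0.12 (0.93 after correction). GPI, glucose-6-phosphate isomerase, rose by 1.38 ± 0.10 (0.98 after correction), and TPI1, triosephosphate isomerase, by 1.66 ± 0.13 (0.65 after correction). Of the 30 genes of this list 20 rose and 3 fell (21 and 4 adjusted over the list alone), with a median of 1.01. For the list, camera's adjusted p was 1.2e-05, and 0.553 with an estimated correlation. The median was 0.45 after correction. Its camera adjusted p was 2.68e-05, and 0.598 with an estimated correlation. Cholesterol synthesis rose in 16 of 26 genes and fell in 7, with MVD at 1.73 ± 0.14 and DHCR7 at 1.46 ± 0.11, each 0.50 after correction. Its median was 1.01, or 0.46 after correction, and its camera adjusted p 0.0153, or 0.553 with an estimated correlation. NRF2 targets rose in 19 of 27 cases and fell in 4 (median 1.0, or 0.32 after correction, camera adjusted p = 0.024, and 0.553 with an estimated correlation). Interferon-stimulated genes went both ways as counted, 20 higher and 22 lower of 49 (median -0.24, camera adjusted p = 0.0841), with TRIM22 (-1.64 ± 0.09), IFIT2 (-2.25 ± 0.14) and IFI44 (-1.74 ± 0.11) lower, or -0.76, -1.46 and -0.69 after correction. After correction 4 members of the list were higher and 18 lower, with a median of -0.17. Camera's adjusted p was then 9.95e-04, and 0.598 with an estimated correlation. The genes with the largest change by rule shrank with the correction, from 1.90 to 0.62 for RRAD, 1.80 to 0.47 for ALKBH7, 1.77 to 0.51 for GALK1, -2.77 to -1.31 for DDX60, -2.65 to -0.97 for LTN1 and -2.60 to -0.74 for GMFB. COL1A1 was at 0.88 ± 0.12 and 0.18 after correction, and ACTA2 at 0.75 ± 0.14 and 0.10. The comparison called 12274 genes, 6391 higher and 5883 lower, 6435 of them at least 2-fold, and 9130 (1507 at least 2-fold) after correction. Of these, 1429 were called in opposite directions, with a rho of 0.82 between log2 fold change and GC content.

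The interaction, the difference between the effects of ethanol with and without inhibitor, was positive for PPFIA4 (4.0 ± 0.45), RRAD (2.99 ± 0.24), SPAG4 (2.96 ± 0.18), SLC16A3 (2.94 ± 0.17), ALDOC (2.77 ± 0.18) and PGK1 (2.53 ± 0.15), with edgeR adjusted p of 1.98e-06 for PPFIA4 and 1.1e-08 for PGK1. It was negative for RAB27B (-3.87 ± 0.29), DDX60 (-3.74 ± 0.31), ZBTB41 (-3.30 ± 0.30), SAMD9L (-3.30 ± 0.28) and CREBRF (-3.20 ± 0.37), and for the interferon-stimulated genes IFIT2 (-3.15 ± 0.19) and IFI44 (-2.78 ± 0.15). After correction these values were 3.32 for PPFIA4, 1.45 for RRAD, 1.53 for SPAG4, 1.91 for SLC16A3, 1.68 for ALDOC and 3.48 for PGK1. They were -1.76 for RAB27B, -2.01 for DDX60, -1.0 for ZBTB41, -1.44 for SAMD9L, -1.10 for CREBRF, -2.20 for IFIT2 and -1.54 for IFI44. In all 11546 genes were called, 5924 positive and 5622 negative, or 8276 after correction, with 1214 called in opposite directions. By list, 21 of 30 hypoxia and glycolysis genes were positive and 2 negative. Their median was 1.81 and their camera adjusted p 8.58e-12, or 0.166 with an estimated correlation. After correction the median was 0.84, with values of 0.77 and 0.997 in the corrected library pairs. Of 49 interferon-stimulated genes 25 were negative and 13 positive, with a median of -0.59 (camera adjusted p = 5.93e-04, or 0.166 with an estimated correlation). After correction 29 were negative and 1 positive, with a median of -0.51 (adjusted p = 0.343 with an estimated correlation).

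Between ethanol plus inhibitor against ethanol and inhibitor against control, which share no library, log2 fold changes correlated across genes at -0.32 as counted and at 0.15 after correction. As counted, 542 genes were higher in both and 613 lower in both, where independent lists would share 1534 and 1634. After correction these numbers were 1229 and 1460, where independent lists would share 1035 and 1196. As counted, 2968 genes were higher in the first comparison and lower in the second, and 2892 the other way round. Independent lists would share 1654 and 1516. After correction these opposite overlaps were 1556 and 920, where independent lists would share 1308 and 947. Spearman's rho was 0.03 after correction, so the inhibitor effects with and without ethanol were not shown to be alike across genes.

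**Figure D4:**
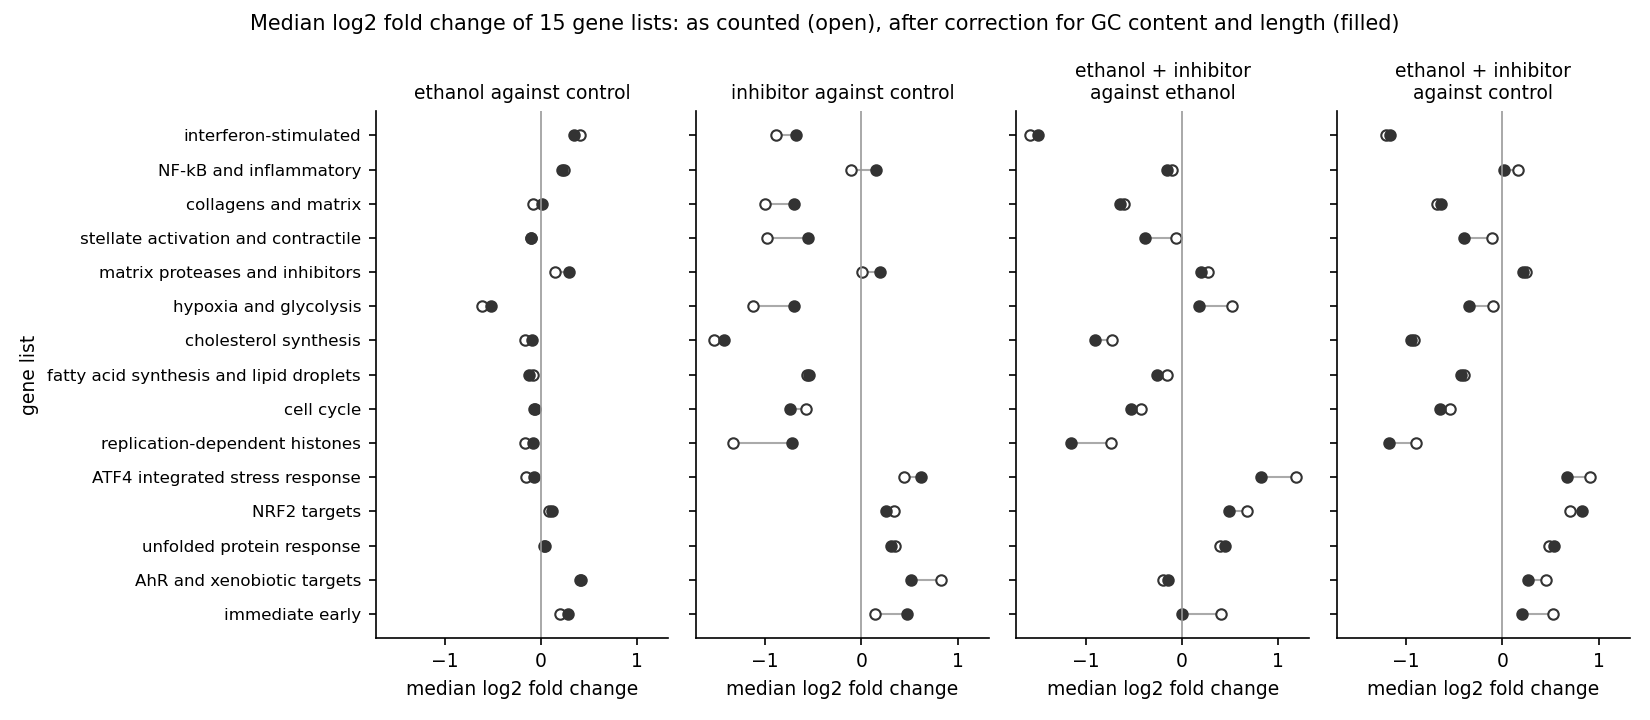
Median log2 fold change (x axis) of the genes of 15 lists (y axis) in 4 comparisons, as counted (open symbols) and corrected for GC content and length (filled symbols). Cholesterol synthesis lies at -1.53 as counted and -1.43 corrected for inhibitor against control, and hypoxia and glycolysis at -0.62 and -0.52 for ethanol against control.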

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

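The tests of GC content, of library pairs, of a wrong label and of other splits of the libraries in this part were chosen after the results were seen, while the test of the interaction and the search for libraries far from the rest of their group were planned.

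Fold changes in every comparison followed GC content, with rank correlations across genes of -0.56 for ethanol against control, 0.69 for ethanol plus inhibitor against ethanol, -0.67 for inhibitor against control, 0.82 for ethanol plus inhibitor against inhibitor, 0.59 for ethanol plus inhibitor against control and 0.80 for the interaction. The treatments alone would leave the ethanol libraries alike, but their own correlations with GC content spanned 0.974, and the difference between ethanol libraries 1 and 2 and ethanol libraries 3 and 4 had a rank correlation of -0.72 with GC content, which a bias of single libraries predicts. Both values describe the split of the ethanol libraries that prompted the test, so the second is no separate support. Libraries of inhibitor-treated cells under the ethanol label are argued against by cholesterol synthesis, whose corrected mean in the lower of ethanol libraries 1 and 2 lay 0.802 (log2) above the highest inhibitor-treated library. A bias in library preparation or sequencing that differed between groups may therefore contribute to the counts of called genes. A treatment effect that itself follows GC content was not tested and stays open, since the correction would remove it too.

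Interferon-stimulated genes were higher with ethanol and lower in every comparison that added the inhibitor to cells without it. A trend in GC content and length as the whole cause is argued against by the corrected median of 0.338 in ethanol against control, and a single pair of libraries per group by the lower of the corrected medians in both pairs, 0.266. The list had an adjusted p of 0.0214 with an estimated correlation after correction in that comparison. A response to ethanol that needs STING is a hypothesis that these values allow. However, the inhibitor also lowered the list without ethanol (median -0.89), so a lower baseline in inhibitor-treated cells stays open. The interaction of the list had an adjusted p of 0.166 with an estimated correlation, and 0.343 after correction, so a difference between the effects of ethanol was not shown for the list.

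Hypoxia and glycolysis genes were lower with ethanol or inhibitor alone, and these falls did not add up with both. For that part, the GC and length trend as the whole cause is argued against by a corrected median interaction of 0.843, and a single pair of libraries by the lower of the corrected medians in both pairs, 0.77. As counted the genes were also less low with both than with ethanol alone, by a median of 0.52 with 20 of 30 higher and 2 lower. After correction this was 0.183, with 9 higher and 2 lower, and no longer past the threshold as the medians shrank, which a GC and length trend predicts. The lower of the corrected medians in both pairs was 0.0186, in libraries 1 and 2, so that part rests on libraries 3 and 4 (0.395). The interaction was not past the threshold with an estimated correlation (adjusted p = 0.166, and 0.343 after correction). Ethanol and inhibitor may each act on this list in a way that does not add up, which is a hypothesis. Differences in cell density, oxygen or medium between cultures could give the same pattern and were not tested, as no label gives them.

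The interaction tests whether the effect of ethanol differed with and without inhibitor, and edgeR called it for 11546 genes, or 8276 after correction, 1214 of them in the opposite direction. Counts simulated with the GC and length trends and no change gave 10938 calls of 15694 genes as counted, so the number as counted does not show how many genes had an interaction. The corrected fit gave 0 calls there, which was fixed in advance because it refits the simulated trend. That 0 says nothing about the 8276 corrected calls. Among the 29 lists tested, those past the threshold were interferon-stimulated genes (median -0.592), ATF4 targets (0.863), cholesterol synthesis (1.26) and hypoxia and glycolysis (1.81), each of which lost its call with an estimated correlation (adjusted p = 0.166, 0.54, 0.166 and 0.166). After correction these medians were -0.51, 0.24, 0.53 and 0.84, and ATF4 targets were no longer past the threshold (adjusted p = 0.148). The genes named by rule with the largest values were PPFIA4 (4), RRAD (2.99), SPAG4 (2.96), SLC16A3 (2.94), ALDOC (2.77), RAB27B (-3.87), DDX60 (-3.74), ZBTB41 (-3.3), SAMD9L (-3.3) and CREBRF (-3.2). After correction they were all smaller, at 3.32, 1.45, 1.53, 1.91, 1.68, -1.76, -2.01, -1.0, -1.44 and -1.10 in this order. Fixed genes past the threshold included ACTA2 (1.58), COL1A1 (1.01), COL1A2 (0.695), TIMP1 (0.968), TGFB1 (1.18), PDGFRB (1.04), MMP2 (1.05), STING1 (1.2), TBK1 (-2.87), IRF3 (1.57), ISG15 (1.17), IFIT1 (-0.592), IL6 (-0.86) and ALDH2 (0.709), and CXCL10 at a fitted -5.98 that depends on the prior count because 1 group is at 0. After correction TGFB1 (-0.20), COL1A1 (0.13), COL1A2 (0.14), MMP2 (0.14), STING1 (0.03), IRF3 (0.14), IL6 (-0.49) and IFIT1 (0.56) were not past the threshold, and TIMP1 (-0.46) and ISG15 (-0.59) were past it in the opposite direction. Still past it were ACTA2 (0.84), PDGFRB (0.26), TBK1 (-1.44), ALDH2 (1.22) and CXCL10 (a fitted -5.39), and CGAS (0.89), CCN2 (-0.53) and CXCL8 (1.14) passed it only after correction. IFIT1 was also not past it without control 1, ethanol 4, ethanol plus inhibitor 4 or inhibitor 3 (-0.505, -0.505, -0.462 and -0.519), nor IL6 without ethanol 4 (-0.75).

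A library lay far from the other 3 of its group in 9 of 224 groups of values examined, a share that chance gives in about 1 in 20 groups. List means are of log2 expression relative to the mean of all libraries, as counted unless said otherwise. That of metallothionein genes was 0.4764 in ethanol library 4 against 0.283 to 0.3132 in the others, and -0.08659 in inhibitor library 1 against -0.2288 to -0.2116. The mean of YAP and SRF targets was 0.1207 in ethanol library 3 against 0.1553 to 0.1578. In ethanol plus inhibitor library 1, genes without a symbol took 0.7547% of the counts against 0.4641 to 0.4987%. There the mean of macrophage and leukocyte markers was 0.5659 against 0.1019 to 0.1533. After correction for GC content and length this mean was -0.07535 against -0.4286 to -0.05957, so library 1 no longer lay apart. In inhibitor library 4 the mean of ethanol and aldehyde metabolism genes was -0.3746 against -0.3298 to -0.3219, and CCL2 was at 14.02 CPM against 15.77 to 16.12. In inhibitor library 2 the mean of aryl hydrocarbon receptor and xenobiotic genes was 0.3596 against 0.4954 to 0.5119. That of cholangiocyte and epithelial markers was -0.3632 against -0.5283 to -0.5068.

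In each pairwise comparison, 1 of the 35 splits of its 8 libraries, the real one, gave as many called genes. That would exclude chance only if the libraries were exchangeable. Libraries 1 and 2 of a group resembled each other, as did libraries 3 and 4, so they were not. Moving such pairs whole leaves 3 splits, too few for a share under 0.05, so these splits cannot exclude chance. The real and the highest other number were 479 and 0 for ethanol against control, 9783 and 0 for inhibitor against control, 12274 and 0 for ethanol plus inhibitor against inhibitor, 8637 and 0 for ethanol plus inhibitor against control, and 10417 and 8288 for ethanol plus inhibitor against ethanol. The 8288 came from exchanging ethanol library 3 with ethanol plus inhibitor library 3, and so many calls in a split point to a structure of the samples. For the interaction the real number was 11546 and the highest other number among 50 splits, the real one included, was 9220. Those splits shuffled the labels of all groups, which also breaks up the separate effects of ethanol and of the inhibitor. They therefore cannot tell whether chance gave the interaction calls.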

How the results depend on the processing

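The GC content and length correction and the fits within library pairs were chosen after seeing the data, and the other alternatives were planned. Of 402 gene results, 399 kept their side of the threshold, and their direction where called, with DESeq2 size factors, 397 with the DESeq2 Wald test, 394 with limma, 393 with no filter, 400 with the stricter filter and 353 after correction, when 18 reversed. Of 174 list results, 174 kept theirs with DESeq2 size factors, 149 after correction and 139 with an estimated correlation, when the number of lists called went from 67 to 32. Small changes can be missed, since 20% of genes changed 1.5-fold were recovered in simulation for ethanol against control.

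For ethanol against control, 479 genes became 821 with no filter, 901 with DESeq2 and 1461 after correction. Within libraries 1 and 2 they were 8039, within libraries 3 and 4 1975, and 3747 and 2700 there with the correction. Single omissions gave 233 to 812, and 287 without control 1, 293 without control 2, 247 without control 3, 258 without control 4, 236 without ethanol 1, 233 without ethanol 2 and 812 without ethanol 3. The 325 reversed genes became 647 with no filter, 814 after correction, 7305 and 1147 within the pairs, and 2622 and 1442 with the correction there, and single omissions gave 148 to 643. Ranges on omission of 1 library were 9421 to 10927 for ethanol plus inhibitor against ethanol, 8785 to 10226 for inhibitor against control, 11871 to 12552 for ethanol plus inhibitor against inhibitor, 7265 to 9651 for ethanol plus inhibitor against control and 11108 to 11902 for the interaction, which fell to 7451 within libraries 3 and 4 with the correction. The correlation of the inhibitor effect with and without ethanol (-0.32) was -0.067 with no filter, 0.148 after correction, 0.00165 within libraries 3 and 4, and 0.0675 and 0.230 within both pairs with the correction, and -0.36 to -0.262 on single omissions. That of the ethanol effect with and without inhibitor (-0.57) was -0.12 with no filter, -0.199 within libraries 3 and 4, and -0.223 there with the correction, and -0.654 to -0.406 on single omissions. The cause was not tested, except that fewer samples entered the fits of pairs and more low-count genes those without filter.

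Some lists and genes called in at least 1 of the fits compared turned direction. NF-kB genes in ethanol against control were at 0.0614 within libraries 1 and 2, with the direction of camera reversed, and mitochondrially encoded genes at -0.094 there and -0.239 with the correction. Heat shock genes within libraries 1 and 2 with the correction were at 0.103 in ethanol against control, -0.00114 in ethanol plus inhibitor against ethanol and 0.21 in inhibitor against control, and mitochondrially encoded genes at 0.221 in ethanol plus inhibitor against ethanol. Immediate early genes were at -0.00243 after correction in ethanol plus inhibitor against ethanol, and for the interaction at -0.324 after correction and -0.309 within libraries 3 and 4 with it (-0.36 within libraries 1 and 2 with it, not past the threshold). Such genes after correction were, in ethanol plus inhibitor against ethanol, TIMP1 (-0.26), TGFB1 (-0.053) and STING1 (-0.124). In inhibitor against control they were TIMP1 (0.196), TGFB1 (0.149) and CGAS (-0.285). In ethanol plus inhibitor against inhibitor they were TIMP1 (-0.091), CCN2 (-0.382), ISG15 (-0.048), IFIT1 (0.753), CXCL8 (1.06) and CCL2 (0.164). For the interaction they were TIMP1 (-0.456), TGFB1 (-0.202), CCN2 (-0.529), ISG15 (-0.587), IFIT1 (0.561) and CXCL8 (1.14). The cause was not tested beyond the correction's own removal of a GC and length trend.

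With the replicate number as a block, 274 genes were called for ethanol against control, 10038 for ethanol plus inhibitor against ethanol, 9255 for inhibitor against control, 12126 for ethanol plus inhibitor against inhibitor, 7905 for ethanol plus inhibitor against control and 11308 for the interaction, and 182 genes reversed. Libraries share only a number: of 24 correlations of deviations between same-numbered libraries, which lay between -0.545 and 0.158, 5 were above 0.1, and 2 of 16 libraries correlated best with their own number.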

Other observations

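The test of gene lists after correction and the fits within library pairs used in this part were chosen after the results were seen. With ethanol against control, metallothioneins and zinc genes rose in 1 of 8 cases (2 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 0.0199, or 0.117 with an estimated correlation). After correction 5 rose and 1 fell (adjusted p = 0.00606 with an estimated correlation). Mitochondrially encoded genes rose in 1 of 13 cases (5 adjusted over the list alone, camera adjusted p = 0.00631, or 0.472 with an estimated correlation). Their median was 0.25, but -0.09 within libraries 1 and 2 and 0.52 within libraries 3 and 4, and 0.20 after correction (camera adjusted p = 0.0484). YAP and SRF targets rose in 1 and fell in 2 of 22 cases (3 and 7 adjusted over the list alone), with the smooth muscle actin gene ACTG2 at -0.78 ± 0.11. Camera gave them an adjusted p of 0.0279, and of 0.157 with an estimated correlation (4.73e-04 and 0.282 after correction). ATF4 targets went both ways, with SLC7A11 higher, 1 gene lower and 5 lower adjusted over the list alone (median -0.16, camera adjusted p = 0.0408, and 0.334 with an estimated correlation). After correction 4 were higher and 4 lower, and camera did not call the list (adjusted p = 0.306). For the 26 genes of cholesterol synthesis, edgeR called 0 (7 at an unadjusted p under 0.05, 1 with DESeq2), with a median of -0.16. Camera gave an adjusted p of 0.0324 for this list, and of 0.225 with an estimated correlation (0.0204 and 0.474 after correction). As counted, camera did not call the cell cycle (adjusted p = 0.0607), fatty acid oxidation and PPAR targets (0.0644), p53 targets (0.149) or the unfolded protein response (0.152). After correction it called the first 3 (0.00108, 0.0219 and 0.00134), with adjusted p of 0.282, 0.282 and 0.0402 with an estimated correlation. As counted it did not call heat shock (0.299), replication-dependent histones (0.299), autophagy and lysosome (0.483), stellate quiescence and retinoid genes (0.689) or ethanol and aldehyde metabolism (0.827) either, nor after correction (0.848, 0.953, 0.788, 0.403 and 0.9). Fry, which tests whether the genes of a list move one way on balance, gave an adjusted p of 1.8e-05 for interferon-stimulated genes. It gave the same for aryl hydrocarbon receptor and xenobiotic genes, and 1.97e-05 for hypoxia and glycolysis. Unlike camera it also called p53 targets (0.0105), cholangiocyte and epithelial markers (0.0234), fatty acid oxidation and PPAR targets (0.0266) and the cell cycle (0.0292), and it did not call ATF4 targets (0.0664) or mitochondrially encoded genes (0.167).

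Of markers of other liver cells, 1 of 17 hepatocyte markers, 5 of 16 macrophage and leukocyte markers, 7 of 13 endothelial markers and 7 of 12 cholangiocyte and epithelial markers had enough counts to be tested. With ethanol the endothelial growth factor receptor gene FLT1 rose (0.79 ± 0.09) and the monocyte marker CD14 fell (-1.16 ± 0.20), and camera called neither endothelial (adjusted p = 0.426), macrophage (0.132) nor cholangiocyte markers (0.103). The inhibitor lowered 3 of 5 macrophage and leukocyte markers (camera adjusted p = 0.00865, or 0.151 with an estimated correlation). After correction camera did not call these markers (adjusted p = 0.105). The inhibitor also lowered 6 of 7 cholangiocyte and epithelial markers and raised 1 (camera adjusted p = 0.0788). Stellate quiescence and retinoid genes rose in 7 of 12 cases with ethanol plus inhibitor against control, with the neurotrophin receptor gene NGFR at 2.56 ± 0.42 (camera adjusted p = 0.0376, or 0.133 with an estimated correlation). After correction camera did not call that list (adjusted p = 0.0948). In inhibitor against control, mitochondrially encoded genes fell in 8 of 13 cases, with MT-CO2 at -0.95 ± 0.10 (camera adjusted p = 0.00525, or 0.502 with an estimated correlation). Ethanol and aldehyde metabolism genes fell in 8 of 13 cases and rose in 2. The list had a camera adjusted p of 0.0237, and of 0.268 with an estimated correlation. The unfolded protein response rose in 15 of 27 cases with 3 lower, and HSPA5 at 1.01 ± 0.09 (camera adjusted p = 0.00227, or 0.335 with an estimated correlation). Autophagy and lysosome genes rose in 18 of 32 cases and fell in 6 with ethanol plus inhibitor against control (camera adjusted p = 1.68e-04). With an estimated correlation the adjusted p was 0.0461, and 0.0595 after correction. Immediate early genes rose in 21 of 29 cases and fell in 1 there, with a median of 0.52 (camera adjusted p = 1.3e-06, or 0.12 with an estimated correlation). After correction 12 rose and 3 fell, with a median of 0.20 (camera adjusted p = 0.00114, or 0.0581 with an estimated correlation). In the same comparison heat shock genes rose in 9 of 17 cases and fell in 2. By camera, the list's adjusted p was 0.0258, and 0.157 with an estimated correlation. After correction camera did not call heat shock genes (adjusted p = 0.188). In the 5 comparisons other than ethanol against control, counts of members adjusted over the list alone differed from those over all genes by at most 3.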
